A study of Homo sapiens with 4 samples.

How the data were processed

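Gene expression was measured on 4 two-colour oligonucleotide arrays (Agilent 4x44K human design) hybridised with RNA from VCaP cells. In every array the labels put the treated sample in the Cy5 (red) channel and its control in the Cy3 (green) channel. The 2 siERG arrays each set cells transfected with small interfering RNA against ERG for 48 h against cells transfected with siControl. The 2 RI-EIP1 arrays each set cells treated with the peptidomimetic RI-EIP1 for 72 h against cells treated with RI-muEIP1. No array had the dyes swapped, so a dye effect specific to a gene or probe enters the ratio of both treatments and cannot be separated from either effect. It cancels only in the difference between the treatments, as far as it was equal on all arrays.

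Per the file headers, the arrays were scanned and read by Agilent Feature Extraction 9.5.1.1, while the submitters' processing notes name version 8.5.1.1. The deposited scanner files held, per spot and channel, the mean signal intensity and the median local background intensity, not normalized. They also held processed signal intensities and a log10 ratio of red over green. Per the file headers, the authors' Feature Extraction run had detrended the processed signals across the array and dye-normalized them by a linear and a lowess step. The log10 ratio equalled that of the processed signals, within 0.001, for 82.2% to 89.6% of spots per array. The setting named Agilent processed signals below used this log10 ratio. The deposited series matrix gave that same log10 ratio for all 43376 spots of each array, within 5e-08, with an array median of 0, so its scale and direction are known and its centring is that of the Feature Extraction dye normalization. Probe coordinates in the files are those of the human genome build hg18.

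The main values were computed from the mean and background intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp (offset 50), and log2 ratios of Cy5 over Cy3 were normalized within each array by loess, with control spots and spots marked as non-uniform at weight 0. Control spots (1639 per array) were then dropped, non-uniform spots were set to missing, and spots of the same probe were averaged. A probe was kept if it was well above background in at least 1 channel on both arrays of at least 1 treatment, which held for 32337 of 41000 probes, and 285 of these were left out because a value was missing. A change in a probe near background is understated by the offset.

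Probes were named by the current symbol of their accession in a RefSeq table of assembly GRCh38.p14, from which no coordinate was taken. This named 23958 probes, a further 2046 took the symbol through another probe with the same name in the file, 3804 kept the name in the file and 11192 had no symbol. Each gene was represented by its brightest probe. This gave 16711 genes, and 7468 probes without a symbol stayed in the fit as rows of their own, for the estimate of the spread only.

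A linear model with 1 mean per treatment was fitted to all 4 arrays (2 residual degrees of freedom), with moderation by eBayes (4.60 prior degrees of freedom). Each treatment's mean log2 ratio was tested against 0, and the RI-EIP1 effect minus the siERG effect was tested likewise, all two-sided with Benjamini-Hochberg adjustment over the 16711 genes and a threshold of 0.05. Standard errors (SE) are those of the moderated fit. Counts of genes changed at least 2-fold on both arrays of a treatment are given beside the calls. The number of arrays limits the precision. The labels call the arrays biological replicates, but the 2 arrays of each treatment lay on 1 slide of their own and were scanned in 1 run. Slide and treatment therefore cannot be told apart in the difference of the effects, and a fit with the slide as a block could not be made. Treatment time (48 h against 72 h) and kind of treatment differ along with it.

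A set of 26 gene lists was fixed before the data were examined, covering ERG-rearranged tumours, the androgen response, epithelial and neuroendocrine lineages, the cell cycle, stress responses, metabolism, signalling and markers of other cell types. Of 687 members looked for, 681 were on the array. Lists were tested with camera at a preset inter-gene correlation of 0.01, which compares a list with all other genes, and again with an estimated correlation. The latter test rests on the 2 residual degrees of freedom and has little power over 26 lists. Its larger p therefore does not by itself show that members of a list move together. For the G2/M list with siERG the estimate was -0.031, under the preset value, and the unadjusted p was still 0.014. Of the lists called below, immediate early (0.0083) and oxidative stress (-0.0056) genes also lay under the preset value. The other called lists lay over it, up to 0.17 for the ERG-rearranged tumour genes. For these the unadjusted p with an estimated correlation was 0.14 with siERG and 0.13 for the difference, so their call rests on the preset value. The test fry, which asks only whether the members of a list move one way on balance, was an alternative. Genes called with siERG were also tested as lists in the RI-EIP1 comparison and the reverse. The rule for named genes was fixed at the same time. It took the 12 largest rises and the 12 largest falls past the threshold with the same sign on both arrays for each treatment, 6 each for the difference, up to 3 members with the smallest p of each list, and 14 genes of prior interest. Some genes that the rule names are not reported here. Genes named outside this rule are said to be so. Genes whose probe was not well above background are said to be so.

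The fit and the list test were tested on simulated log ratios with the spread of the real fit. In the siERG comparison over 16711 genes, 36% of genes changed by 0.25 (log2), 94% of those changed by 0.5 and 100% of those changed by 1 were recovered, with 4 false calls. The RI-EIP1 comparison gave 48%, 96% and 100%, with 11 false calls. A list that was shifted in the simulation was called in both comparisons, and no other list was. These simulations held no dye effect. They changed only 50 genes at each size and a single list, against 7737 (siERG) and 6187 (RI-EIP1) genes called in the data. With so few changed genes the adjusted threshold is stricter, so the recovery of small changes cannot be carried over to the data. Genes were drawn independently of each other, so the list test was not checked for correlated genes.

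Alternatives covered the background correction, the normalization, the filter on dim probes, saturated probes, the choice of probe, the eBayes options, the arrays in the fit, a replicate block, leaving out each array, the series matrix values, the thresholds and the set tests. A test against a minimum fold of 1.5 and lists of genes changed at least 2-fold were added after the data had been seen.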

Results

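VCaP is a prostate cancer cell line that carries the TMPRSS2:ERG gene fusion, through which the transcription factor ERG is overexpressed. RNA from these cells was compared on 4 two-colour arrays, 2 for each of the treatments. The first treatment lowered ERG mRNA with small interfering RNA (siERG against siControl, 48 h, n = 2 arrays). The second used RI-EIP1, a peptidomimetic that per the labels destabilises the ERG protein, against the control peptidomimetic RI-muEIP1 (72 h, n = 2 arrays). Each array held the treated sample in Cy5 and its own control in Cy3, and each value below is the log2 ratio of treated over control. Between 71.5% and 81.4% of spots were well above background in Cy5 and between 67.0% and 79.1% in Cy3. Log ratios of the replicate arrays correlated across the 16711 genes with r = 0.92 for siERG and r = 0.83 for RI-EIP1.

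ERG itself was examined first, as the target of the knockdown. With siERG, the 2 brighter of its 3 probes on chromosome 21 fell to 30.1% (38676351 to 38676410, hg18) and 26.3% (38696356 to 38696415) of the siControl level, with log2 ratios of -1.73 (SE 0.038, single arrays -1.71 and -1.75) and -1.93 (SE 0.043). The third and dimmer probe (38677643 to 38677702) had a ratio of -0.44 (SE 0.042). The files do not place these probes in an exon or untranslated region. With RI-EIP1, ERG mRNA stayed near its control level, at -0.17 (SE 0.037, adjusted p = 0.015) for the brightest probe, and the other probes read -0.09 and, for the dimmer one, -0.30. The call of the brightest probe was lost without either RI-EIP1 array and with the Agilent processed signals, and the value was 0.28 when arrays were centred on their median instead of normalized by loess. The difference between the treatments was 1.57 (SE 0.053, adjusted p = 1.9e-05) for the brightest probe and 1.84 for the second, but the dimmer probe read 0.13 and did not pass (adjusted p = 0.14).

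The siERG comparison asked which genes change when ERG is knocked down. The largest fall was that of PLAT, tissue-type plasminogen activator, which was 10.3-fold lower (log2 ratio -3.37, SE 0.036, adjusted p = 2.0e-07). SLC16A3, which exports lactate, fell 7.54-fold (-2.92, SE 0.037), and the long non-coding RNA LINC00261 had a ratio of -2.19. IGFBP3, which binds insulin-like growth factors, fell with -2.14, the sialyltransferase gene ST3GAL1 with -2.09, the growth factor gene PDGFC with -1.99 and ARHGDIB with -1.77. MRPS16, PFDN6, GALNT18 and CCNJ completed the 12 largest falls together with ERG, at -2.00, -1.97, -1.66 and -1.64. The largest rises were those of TMEFF2, which encodes a transmembrane protein with follistatin-like domains (3.38, SE 0.039), MAGEH1 (2.63), the prostaglandin-degrading enzyme gene HPGD (2.56), the arginase gene ARG2 (2.49), the relaxin gene RLN1 (2.42) and SLC45A3, which encodes the prostate protein prostein (2.38). SI, ALB, USP51, FOLH1, PSMAL and TFF1 followed, with ratios between 1.73 and 2.02. FOLH1 encodes prostate-specific membrane antigen, and PSMAL is its close copy, so their probes can read both transcripts. A second, dimmer probe disagreed for TMEFF2 (-0.02), and the other probes read 0.27 for ALB, -0.34 for PDGFC and -0.09 for GALNT18.

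Of the genes of prior interest, SOX9 fell with siERG (-0.88, SE 0.037) and MYC fell (-0.53, SE 0.036), although another MYC probe read 0.08. TMPRSS2, the androgen-regulated partner of the fusion, rose by 1.41 (SE 0.053), and EZH2 rose by 0.17 (SE 0.047). KLK3, which encodes prostate-specific antigen, read 0.20 on its brightest probe, but its 3 probes ranged from -0.56 to 0.20 and their mean was -0.22, so no direction is given. TDRD1 (-0.38), CACNA1D (-0.21) and ETS1 (-0.14) fell, ETS1 not being well above background in either channel and reading 0.084 (adjusted p = 0.27) without the filter on dim probes. The urokinase gene PLAU (0.10, SE 0.048, adjusted p = 0.15) did not pass. FLI1 and ETV1 had no probe that was kept, so they were not among the genes tested.

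Mitotic genes rose together with siERG. Of 32 genes of G2/M and mitosis, 30 rose, none fell and 2 did not pass, with a median of 0.39, as for HMMR (0.74), CENPE (0.62) and the survivin gene BIRC5 (0.55). The camera adjusted p was 5.6e-12 (0.36 with an estimated correlation). Genes of hypoxia and glycolysis fell: 22 of 27 fell, none rose and 5 did not pass, with a median of -0.45, as for the angiogenic factor gene VEGFA (-1.21), PFKFB4 (-1.06) and PFKFB3 (-1.01, another of its probes 0.70). The adjusted p was 3.7e-09 (adjusted p = 0.45 with an estimated correlation). Androgen response genes rose on balance, 21 rising, 8 falling and 8 not passing of 37, with a median of 0.20, led by HPGD, SLC45A3 and TMPRSS2. The adjusted p was 0.00044 (adjusted p = 0.47 with an estimated correlation).

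Genes known to be high in ERG-rearranged prostate tumours fell with siERG. Of 17 measured, 12 fell, 2 rose and 3 did not pass, with a median of -0.22, as for ARHGDIB, the phospholipase gene PLA1A (-1.44, SE 0.038) and HLA-DMB (-1.18, SE 0.036), and the adjusted p was 0.00018 (adjusted p = 0.53 with an estimated correlation). The list of Notch and Wnt target genes, which also holds receptors and ligands of these pathways, was lower, with 11 falling, 4 rising and 7 not passing of 22. It was led by the Wnt receptor gene FZD4 (-1.05), the ligand gene WNT2 (-0.92) and HES1 (-0.75). The camera adjusted p was 0.0498 (adjusted p = 0.53 with an estimated correlation). That call was lost without either siERG array, with no background subtraction, with either other filter and with the mean of all probes. Cytosolic ribosomal protein genes were higher on their brightest probes, with 24 rising, 3 falling and 9 not passing of 36 and a median of 0.19 (adjusted p = 2.6e-05, and adjusted p = 0.47 with an estimated correlation). Their call ended with the Agilent processed signals (median 0.037, adjusted p = 0.36), and the other probes of the same genes had a median of -0.062. Random lists of equally bright genes had a median of 0.082 with siERG and a highest median of 0.23, so the median of the ribosomal list lay within their range. Adjusted over the list alone, the G2/M, hypoxia and ribosomal counts were the same, 13 of the ERG-rearranged tumour genes and 12 of the Notch and Wnt genes fell, and 24 of the androgen response genes rose and 9 fell. Markers of basal cells, fibroblasts, endothelium and leukocytes were not called as lists by camera, with adjusted p of 0.81, 0.89, 0.45 and 0.53, while fry called the endothelial and basal lists lower (adjusted p = 0.0082 and 0.016). The endothelial list holds ERG itself, so its fall includes the knockdown. Of its 12 members, 2 fell, 1 rose and 9 did not pass.

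In all, 7737 genes (46.3%) passed with siERG, 3746 higher and 3991 lower, and their median absolute log2 change was 0.23. Only 55 rose and 55 fell at least 2-fold on both arrays, and a test against a 1.5-fold minimum, added after the data had been seen, called 104 higher and 138 lower. With median centring 10491 genes passed, 7896 higher and 2595 lower. The p-values rest on the small spread between the 2 arrays within each treatment, pooled over both and moderated, and include any dye effect of a probe. Among 3216 called genes with several probes, 31.6% had probes of opposite sign, and among those changed at least 2-fold 8 of 51 did.

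**Figure D1:**
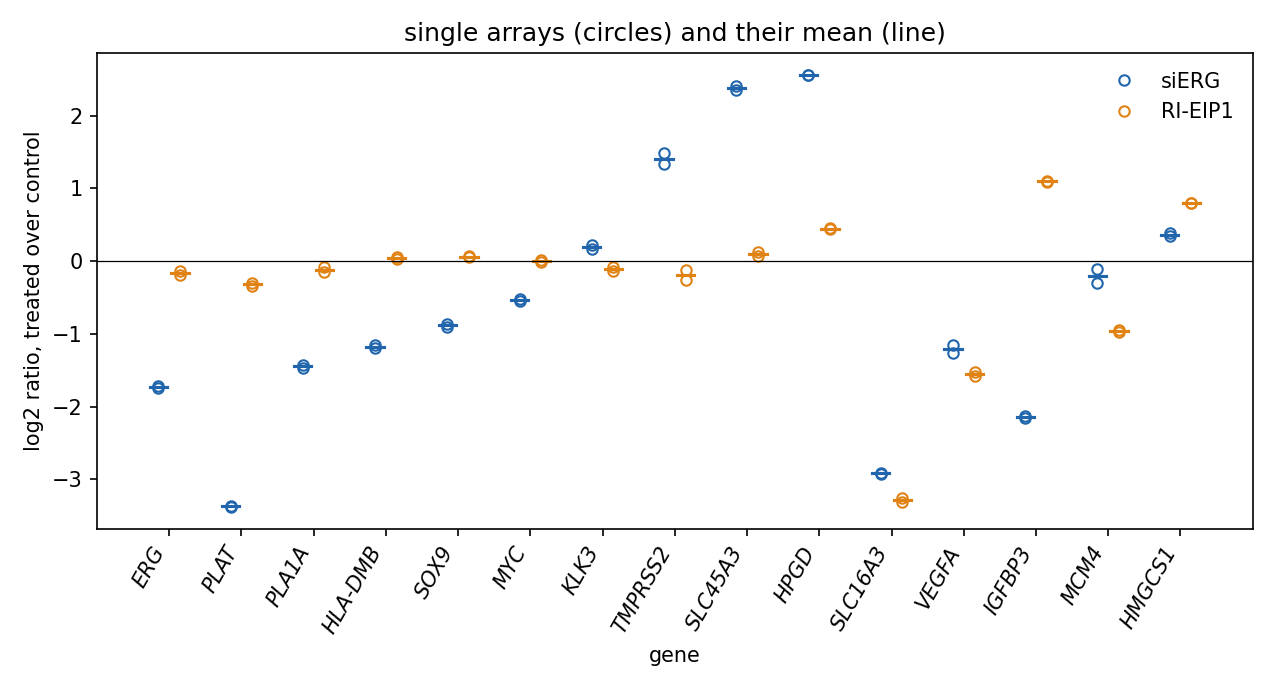
Log2 ratios of treated over control (vertical axis) for 15 genes, with siERG arrays in blue and RI-EIP1 arrays in orange; circles are single arrays (n = 2 per treatment) and the line is their mean. ERG, PLAT and PLA1A lie far below 0 with siERG and near it with RI-EIP1 (ERG with RI-EIP1 at -0.17, and at 0.28 under median centring), while SLC16A3 and VEGFA lie below 0 with both.

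The RI-EIP1 comparison asked which genes change with the ERG-directed peptidomimetic relative to its control. The largest fall was that of SLC16A3, 9.71-fold lower (-3.28, SE 0.037, adjusted p = 3.3e-07). KRT80, a keratin gene, fell with -2.39, but its other probe read 0.56. The collagen lysyl hydroxylase gene PLOD2 fell with -2.02, TMED9 with -1.87, HNRNPA0 with -1.75, the cytokine-signalling suppressor gene SOCS3 with -1.65 (its other probe -0.11) and VEGFA with -1.55 (SE 0.043). PKD1L2 (its other probe -0.05), IGKV2-24, BIRC7, DLST and CCKBR fell with ratios between -1.73 and -1.46. The largest rises were smaller, led by the calcium-binding protein gene S100P (1.45, SE 0.040), RPS27A (1.44, SE 0.277, single arrays 2.15 and 0.74), RPS2 (1.31, its 6 probes ranging from -0.35 to 1.31) and UBE2E1 (1.27). The place of RPS27A rests on replicate 1, and its call was lost with the Agilent processed signals (adjusted p = 0.13) and with robust moderation (adjusted p = 0.097). They included IGFBP3 (1.09, SE 0.035), the extracellular matrix gene SPON2 (1.07), PLAAT3 (0.99) and the ribosomal genes RPL13A, RPS27, RPL14, RPL7 and the pseudogene RPLP0P2, with ratios between 1.00 and 1.14, while another RPL7 probe read 0.07. Ribosomal protein genes have many processed pseudogenes whose transcripts a probe can also read.

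Of the genes of prior interest, PLAT fell with -0.32 (SE 0.036) and TDRD1 with -0.21. TMPRSS2 (-0.20) and EZH2 (-0.17) fell as well, but both were higher, at 0.22 and 0.16, when arrays were centred on their median. SOX9 (0.06), MYC (0.00), PLAU (0.05), CACNA1D (-0.08), ETS1 (0.02) and KLK3 (-0.11) did not pass, but with median centring ETS1 was lower (-0.24) and KLK3 higher (0.45), both past the threshold.

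Genes of G1/S and DNA replication fell with RI-EIP1. Of 29, 28 fell and 1 rose, with a median of -0.42, as for the replicative helicase gene MCM4 (-0.96), its loading factor CDC6 (-0.78) and CDC45 (-0.70), and the adjusted p was 2.9e-15 (adjusted p = 0.25 with an estimated correlation). Hypoxia and glycolysis genes fell, 21 of 27, with 1 rising and 5 not passing and a median of -0.53, as for VEGFA, PFKFB4 (-1.28) and PFKFB3 (-1.03). The adjusted p was 1.8e-12 (adjusted p = 0.25 with an estimated correlation). The median of the other probes of such genes was -0.41 in this comparison and also -0.41 with siERG. Cytosolic ribosomal protein genes rose on their brightest probes, 33 of 36, with 1 falling and 2 not passing and a median of 0.58 (adjusted p = 4.2e-18, and adjusted p = 0.25 with an estimated correlation). Random lists of equally bright genes had a median of 0.23, and the other probes of 21 of the ribosomal protein genes had a median of 0.10.

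Smaller shifts were called in 4 further lists, with medians between -0.062 and 0.19. Cholesterol and fatty acid synthesis genes rose, 17 rising, 5 falling and 8 not passing of 30, as for HMGCS1 (0.80), INSIG1 (0.58) and SQLE (0.41), with an adjusted p of 0.0025. Immediate early genes rose, 14 rising, 2 falling and 16 not passing of 32, as for SPRY4 (0.55) and JUN (0.40), while CCN1 fell (-0.65), with an adjusted p of 0.038. Androgen response genes were higher, 16 rising, 5 falling and 16 not passing of 37, as for PTGER4 (0.66), EAF2 (0.66) and HPGD (0.45), with an adjusted p of 0.038. Oxidative stress and metal response genes were lower, 10 falling, 3 rising and 14 not passing of 27, as for the metallothionein genes MT1M (-0.48) and MT1H (-0.39), with an adjusted p of 0.043, but the list was at 0.19 and MT1H at 0.029 when arrays were centred on their median. With an estimated correlation the adjusted p was 0.42 for all 4. The immediate early call was lost without RI-EIP1 replicate 2, with the Agilent processed signals, with no background subtraction, with median centring and with either other filter. The androgen response call was lost without either siERG array, with the Agilent processed signals and with the mean of all probes, and the oxidative stress call without either RI-EIP1 array, with no background subtraction, with the stricter filter and with the mean of all probes. Adjusted over the list alone, 22 hypoxia genes fell and 1 rose, 14 immediate early genes rose and 4 fell, 20 androgen response genes rose and 7 fell, and 10 oxidative stress genes fell and 4 rose, with the counts of the other called lists as given.

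In all, 6187 genes (37.0%) passed with RI-EIP1, 3134 higher and 3053 lower, with a median absolute log2 change of 0.21. At least 2-fold on both arrays, 7 rose and 35 fell, and the test against a 1.5-fold minimum called 21 higher and 50 lower. The count was 3228 without replicate 1 and 3844 without replicate 2, 2760 with the Agilent processed signals, and 11810 with median centring, when 9130 were higher. Among 2414 called genes with several probes 36.5% had probes of opposite sign, and any dye effect of a probe would enter these values too.

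**Figure D2:**
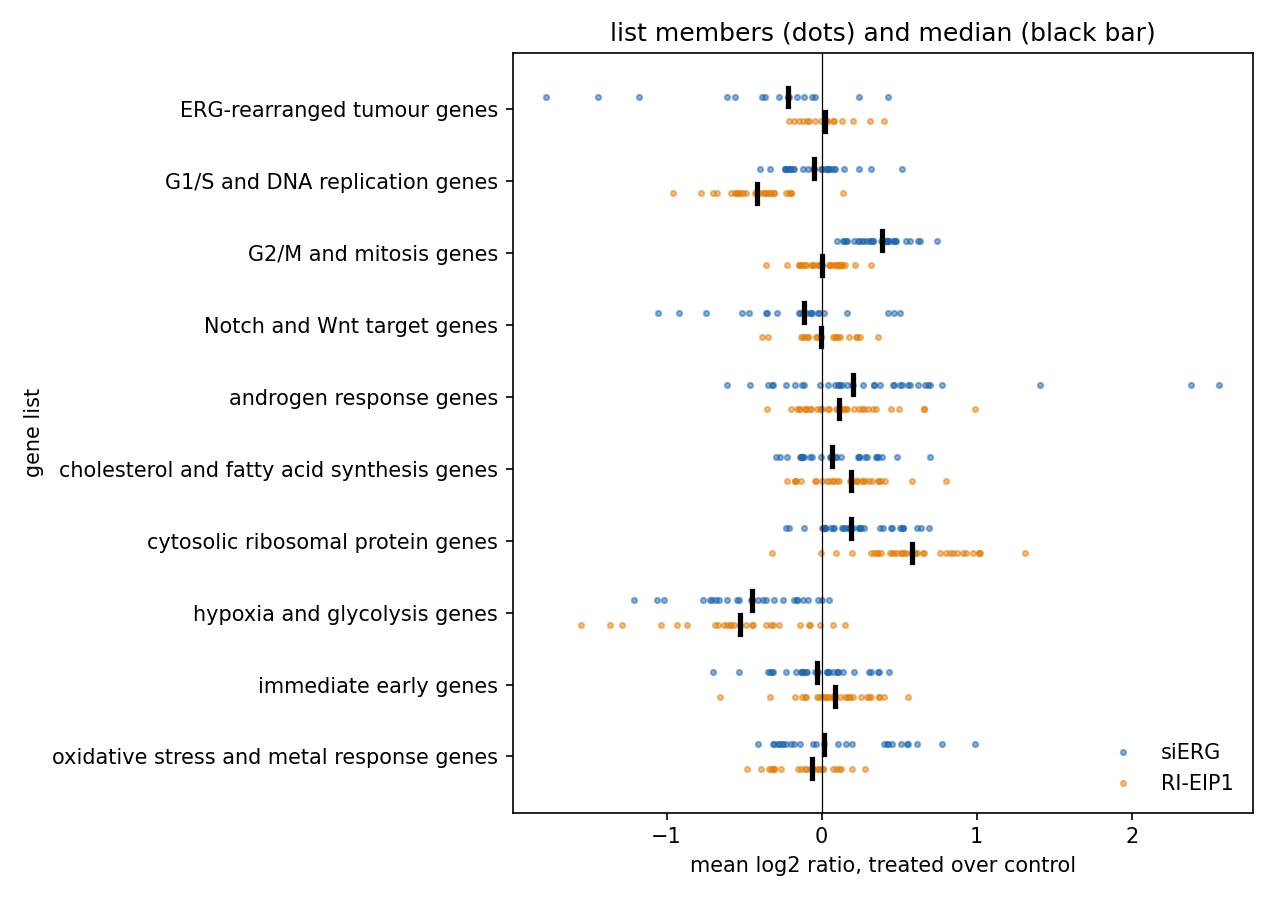
Mean log2 ratios of the members (dots) of the 10 gene lists called in at least 1 comparison, with siERG in blue and RI-EIP1 in orange; the black bar is the median of the list. Hypoxia and glycolysis genes lie below 0 with both treatments (medians -0.45 and -0.53), whereas the G2/M median is 0.39 with siERG and 0.0051 with RI-EIP1, and the G1/S median is -0.42 with RI-EIP1.

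The remaining 16 lists were called by camera in no comparison, with a smallest adjusted p of 0.058 for the mitochondrial respiratory chain with siERG. They were the lists of invasion and mesenchymal genes, luminal, basal and neuroendocrine markers, MYC and ribosome biogenesis, interferon response, p53 targets, unfolded protein response, heat shock, NF-kB, ETS family, mitochondrial respiratory chain and histone genes, and the markers of fibroblasts, endothelium and leukocytes. The invasion list holds PLAT and SOX9, but with siERG only 5 of its 24 members fell and 4 rose (median 0.0012). The test fry, which does not compare a list with other genes, called 10 of the 16 with siERG. Among them the mitochondrial (adjusted p = 0.0025), invasion (0.0037), ETS (0.0069), endothelial and basal lists were lower, and the interferon, heat shock and histone lists higher. ERG, the target of the knockdown, is a member of the ETS and endothelial lists, so their fall includes its own (-1.73). The median of the ETS list was 0.011. With RI-EIP1 fry called 3, the luminal (0.015, lower), fibroblast (0.037, higher) and endothelial (0.037, lower) lists. With RI-EIP1 the other-cell markers of fibroblasts, endothelium and leukocytes had camera adjusted p of 0.42, 0.077 and 0.77. Among median, mean and test the sign differed for the ETS, invasion, fibroblast and neuroendocrine lists with siERG, for the unfolded protein, ETS, Notch and Wnt, mitochondrial and histone lists with RI-EIP1, and for the interferon, endothelial, p53 and neuroendocrine lists in the difference.

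The treatments were then compared with each other, since both are directed at ERG. PLAT was higher with RI-EIP1 than with siERG by 3.05 (SE 0.051), IGFBP3 by 3.24, PLAAT3 by 2.54, LINC00261 by 2.20, ST3GAL1 by 2.04 and MRPS16 by 1.93, and TMEFF2 (-3.00), ARG2 (-2.65), MAGEH1 (-2.57), RLN1 (-2.53), SLC45A3 (-2.29) and ALB (-2.22) were lower. IGFBP3 was the 1 gene changed at least 2-fold in opposite directions. The shift of the ERG-rearranged tumour genes differed by a median of 0.30 (10 of 17 higher with RI-EIP1 than with siERG, 1 lower, adjusted p = 4.4e-05, and adjusted p = 0.53 with an estimated correlation), as for ARHGDIB (1.63), PLA1A (1.32) and HLA-DMB (1.22). Against RI-muEIP1 this list was not called (camera adjusted p = 0.92), with 4 members rising, 4 falling and 9 not passing and a median of 0.021. Lower with RI-EIP1 than with siERG were G2/M genes (28 of 32, median -0.34, adjusted p = 3.5e-12) and G1/S genes (23 of 29, median -0.37, adjusted p = 5.9e-11), while ribosomal protein genes were higher on their brightest probes (30 of 36, median 0.36, adjusted p = 8.2e-12). With an estimated correlation the adjusted p was 0.35 for these 3 lists. Androgen response genes were lower on balance (20 of 37, 10 higher, median -0.21, adjusted p = 0.031) and immediate early genes higher (14 of 32, 4 lower, median 0.14, adjusted p = 0.036), each with an adjusted p = 0.53 with an estimated correlation. The immediate early call was lost without siERG replicate 2, without RI-EIP1 replicate 2, with the Agilent processed signals and without the filter on dim probes, and both it and the androgen response call were lost with median centring and with the stricter background filter. Adjusted over the list alone, 12 ERG-rearranged tumour genes were higher and 2 lower, 29 G2/M and 25 G1/S genes lower and 32 ribosomal protein genes higher, with the other counts as given. The hypoxia list did not pass (median -0.17, adjusted p = 0.13), but did without RI-EIP1 replicate 1 (adjusted p = 0.026) and with loess and scale between arrays (adjusted p = 0.032). In all, 5533 genes differed, 2823 higher and 2710 lower with RI-EIP1, and 48 and 48 by at least 2-fold in every pairing of arrays. Without siERG replicate 1 the count was 3576, and time, slide and kind of treatment differ with the treatments.

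Across genes the log ratios of the treatments correlated with r = 0.34 (Spearman correlation 0.33; genes are not independent replicates; r = 0.592 with median centring), and 61.7% of genes had the same sign. Genes called higher in both numbered 1408, where independent calls would give 702.5, and genes called lower in both 1436 against 729.1. Opposite calls numbered 454 (lower with siERG and higher with RI-EIP1, 748.5 if independent) and 354 (684.4 if independent). As lists in the RI-EIP1 comparison, the 3991 genes called lower with siERG had a median of -0.065 (camera p = 3.0e-10, and p = 0.014 with an estimated correlation) and the 3746 called higher a median of 0.082 (camera p = 4.1e-10, and p = 0.022 with an estimated correlation). Lists of genes changed at least 2-fold were added after the data had been seen. All 35 genes that fell at least 2-fold with RI-EIP1 were called lower with siERG (median -0.66). The 55 genes that fell at least 2-fold with siERG had a median of -0.12 with RI-EIP1, where 28 were called lower and 11 higher (camera p = 1.6e-05, and p = 0.033 with an estimated correlation). The 55 that rose had a median of 0.15, with 26 called higher and 6 lower (camera p = 1.4e-05, but p = 0.074 with an estimated correlation), and the 7 that rose with RI-EIP1 had p = 0.080 with an estimated correlation in siERG. Genes that fell at least 2-fold in both were SLC16A3, VEGFA, PFKFB3, PFKFB4, DDIT4, LMNB1, IGF2 and LOC57400, and S100P and SPON2 rose in both; those outside the rule were named after their values were seen. Any dye effect shared by the arrays would add to such agreement. Between different probes of the same gene, in 5621 genes, the treatments correlated with r = 0.099, against 0.335 for the same probe.

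**Figure D3:**
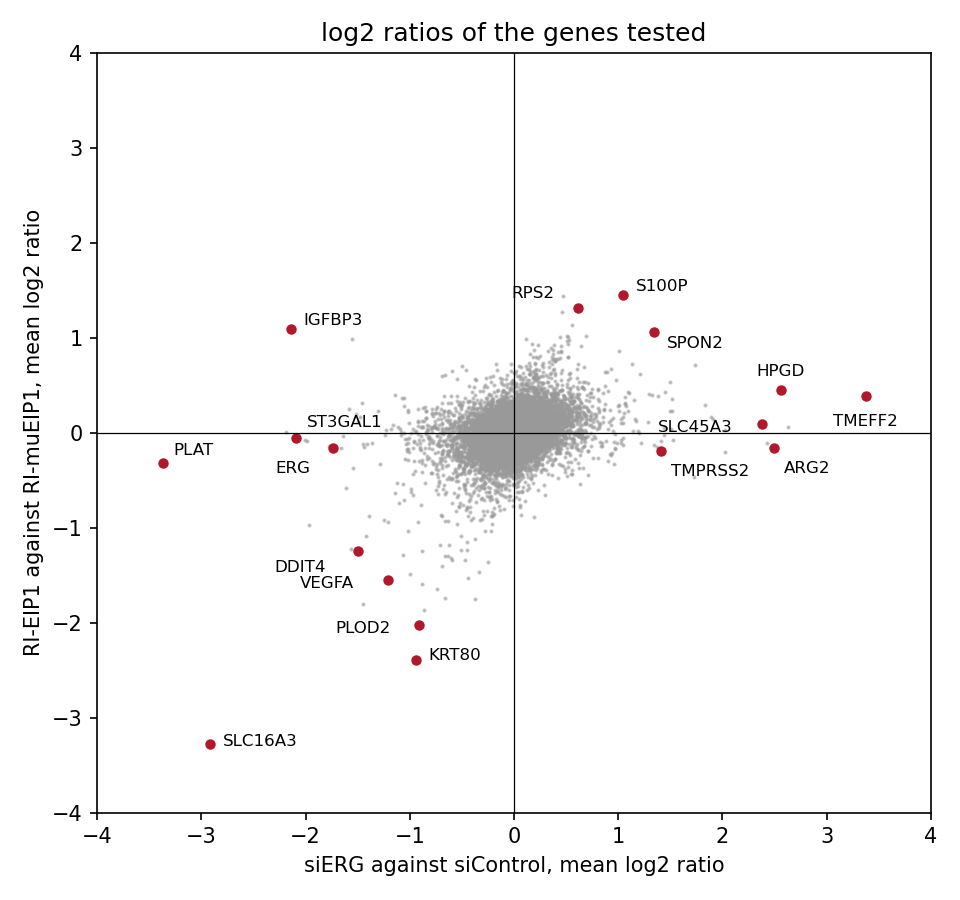
Mean log2 ratio with siERG (horizontal axis) and with RI-EIP1 (vertical axis) for each of the 16711 genes (grey) with named genes in red; each mean is over 2 arrays. SLC16A3 lies at -2.92 and -3.28, PLAT at -3.37 and -0.32, and IGFBP3 at -2.14 and 1.09.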

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

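The tests of a whole-transcript dye effect, of the share of the covariance between probes, of a common dye effect and of a brightness trend as the whole cause were chosen only after the result was seen. For a probe-specific dye effect on the correlation, the bound set in advance (r and the lower end of its interval over 0.1) was not met, and the reading below rests on a looser bound of 0.05, applied after the value was seen. For the hypoxia genes the bound set in advance (a median under -0.2 with both treatments) was met, but the interval with siERG, computed afterwards, reached past it and stayed only under -0.1.

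A test of the difference between the treatments flagged 5533 genes. The ERG mRNA difference was 1.57, and the 6 largest differences in the same direction were those of IGFBP3 (3.24), PLAT (3.05), PLAAT3 (2.54), LINC00261 (2.20), ST3GAL1 (2.04) and MRPS16 (1.93), and SOX9 differed by 0.95. The brightest MYC probe read 0.53, but its 3 probes ranged from -0.07 to 0.53, so no direction is given. In the other direction lay TMEFF2 (-3.00, its other probe 0.05), ARG2 (-2.65), MAGEH1 (-2.57), RLN1 (-2.53), SLC45A3 (-2.29), ALB (-2.22), TMPRSS2 (-1.60) and EZH2 (-0.34). The brightest KLK3 probe read -0.30, but its 3 probes ranged from -0.30 to 0.13, so no direction is given. The lists that differed had median differences of 0.30 (ERG-rearranged tumour genes), -0.21 (androgen response), -0.37 (G1/S), -0.34 (G2/M), 0.36 (ribosomal protein genes) and 0.14 (immediate early genes). Among single probes with no gene symbol, which no comparison counts, 24 changed at least 2-fold on both arrays with siERG (7 higher, 17 lower) and 17 with RI-EIP1 (all lower).

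The siERG and RI-EIP1 log ratios correlated across genes, with r = 0.34. A biological effect shared by both treatments, through ERG or not, or a dye effect in both would give this. Between different probes of the same gene r was 0.099 (95% interval 0.067 to 0.128, 5621 genes), which lies above what a probe-specific dye effect as the whole cause allows. The covariance across different probes was 28.8% (21.2% to 35.7%) of that of the same probe, so that effect may be the larger part. Within a treatment, the covariance across different probes was 52.0% (siERG) and 36.8% (RI-EIP1) of the variance of the same probe. A probe-specific dye effect would lower these shares too, so they do not separate it from other reasons for probes to disagree. A dye effect of the whole transcript (r = 0.34) and a biological effect cannot be told apart without an array with swapped dyes.

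Cytosolic ribosomal protein genes rose with RI-EIP1 by a median of 0.58. A brightness trend as the whole cause is argued against by 10000 random lists of equal brightness, whose highest median was 0.46. A dye effect of equal size on all arrays is argued against by the difference from siERG, with a median of 0.36. That difference cannot decide on a dye effect that differed between the slides, since each slide held 1 treatment. Random lists of equal brightness also differed between the treatments, with medians of 0.23 (RI-EIP1) and 0.082 (siERG). As a part of the cause a brightness trend stays open, since the random lists had a median of 0.23, between the bounds set in advance. The other probes of 21 of these genes had a median of only 0.10 (0.07 to 0.28), where the brightest probes of the same genes had 0.59. That median met the bound set in advance for an effect of the brightest probes alone, but its interval reached past the bound. On the other probes 18 of these genes were higher and 3 lower, so a smaller rise beyond the brightest probes stays open. A change in ribosomal protein mRNA was not tested in another way.

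Hypoxia and glycolysis genes fell with both treatments (medians -0.45 and -0.53). Random lists of equal brightness had a median of 0.0031 with RI-EIP1 and 0.0028 with siERG, which argues against a brightness trend. The other probes of 14 of these genes had medians of -0.41 with siERG (-0.53 to -0.12) and -0.41 with RI-EIP1 (-0.69 to -0.23), which argues against a dye effect of single probes. A dye effect of whole transcripts, a difference between treated and control cultures in density or oxygen, and an effect through ERG stay open and were not tested.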

How the results depend on the processing

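The test against a minimum fold of 1.5 and the lists of genes changed at least 2-fold were chosen only after the result was seen. ERG with siERG kept its direction and its call under every setting (-1.75 to -1.71 without single arrays). Where a replicate is left out, the lone array is assumed to vary like the others. Without single arrays, the counts ranged from 5248 to 7759 for siERG, 3228 to 6094 for RI-EIP1 and 3576 to 4411 for the difference, ERG with RI-EIP1 from -0.19 to -0.14 (call lost without either RI-EIP1 array, adjusted p = 0.0621 and 0.154), the agreement from 0.313 to 0.351, and called lists from 5 to 6, 5 to 7 and 5 to 7. The siERG calls as lists in RI-EIP1 ranged from 0.081 to 0.101 (higher) and from -0.077 to -0.067 (lower). The cause of these and the following changes was not tested.

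With the Agilent processed signals, and with the series matrix that holds the same values, the counts were 2760 for RI-EIP1 and 3584 for the difference, the agreement was 0.306 and ERG with RI-EIP1 was -0.14 (adjusted p = 0.105). With median centring instead of loess, 11810 genes passed with RI-EIP1 and 77.3% of them were higher (75.3% of 10491 with siERG), the agreement was 0.592, and 16 lists (siERG) and 11 (RI-EIP1) were called. The median of all genes then lay at 0.109 (siERG) and 0.158 (RI-EIP1). That setting turned ERG with RI-EIP1 to 0.28. It also turned, with siERG, HSPA4 (0.0012), ATP5F1B (0.18) and COX7A2 (0.27), and with RI-EIP1 MT1H (0.029), TRIB3 (0.14), MT1B (0.056), CD24 (0.040), ATP5F1B (0.26), SOX17 (0.073), CDK1 (0.16), PSMB9 (0.0074), TMPRSS2 (0.22), EZH2 (0.16), KLK3 (0.45), ETS1 (-0.24) and KRT6A (-0.18, not well above background in the control). Of the lists called under either setting, those that turned were G1/S (siERG, 0.28), the mitochondrial respiratory chain (0.31 with siERG, 0.47 with RI-EIP1) and oxidative stress (RI-EIP1, 0.19). Relative to the median of all genes, 9 of these 17 genes and 3 of these 4 lists stayed turned. Without the filter, ETS1 with siERG was 0.084. With the mean of all probes, KLK3 (-0.22) and RFC3 (-0.18) with siERG and NPM1 with RI-EIP1 (-0.094) turned. For the endothelial list in the difference (median -0.083 in both), the direction of fry was up and that of camera down.

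A log2 change of at least 1 on both arrays left 110, 42 and 96 genes, and the 1.5-fold minimum 242, 71 and 158. With an estimated correlation 0 lists were called in siERG, 0 in RI-EIP1 and 0 in the difference, and with fry 19, 10 and 15. The test with an estimated correlation rests on 2 residual degrees of freedom, so this loss does not show that members of a list move together. For genes named, 5152 values under other settings kept the call and its direction or passed in neither setting, whatever their sign. A further 330 lost the call, 202 of them under the log2 minimum of 1, while 30 gained it and 21 turned. For lists these numbers were 1145, 53, 45 and 5. The Agilent processed signals and the series matrix hold the same values and were both counted. Replicate numbers do not pair the arrays (correlation of the deviations 0.0119), and with a replicate block the counts were 7595, 5956 and 5298. A slide block was not run, since each slide holds 1 treatment. Signal over background limits dim genes, with 67.0% to 79.1% of spots well above background in Cy3.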

Other observations

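The test of liver and intestinal genes was set up on a list of other such genes after the genes that prompted it had been seen. Genes named in this part that the report does not name were chosen after their values were seen.

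With siERG, LINC00261 (-2.19) and its neighbour on chromosome 20, the transcription factor gene FOXA2 (-1.49), both fell. The microRNA-processing enzyme gene DICER1 rose 2.82-fold, while DNAJC7 (-1.39) and FBXW11 (-1.54) fell. The nuclear lamina gene LMNB1 fell with siERG (-1.56) and with RI-EIP1 (-1.22), as did the growth factor gene IGF2 (-1.42 and -1.09). Of the metallothionein genes, whose transcripts are alike enough for probes to read several of them, MT1F (0.99), MT2A (0.78) and MT1B (0.62) rose with siERG, and no test of these genes as a group was made.

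Several genes of liver and intestine were among the rises with siERG: ALB (2.02), SI (2.02), TFF1 (1.73), MAT1A (1.44), UGT2B4 (1.41), SPINK1 (1.21) and APOH (0.91). The hypothesis that such genes rise as a group was tested on 43 others, of which 29 were measured. FOXA2 was among the 43 although its fall had been seen. The camera p was 0.0343 for a rise with siERG, but the p was 0.139 with an estimated correlation. The median was 0.07, with 10 genes rising, as for TTR (1.17), REG4 (0.93) and DPP4 (0.65), 4 falling and 15 not passing. With RI-EIP1 the p was 0.366, and for the difference between the treatments 0.131. The rise thus held only with the preset correlation. The test with an estimated correlation has only 2 residual degrees of freedom and cannot decide it, and a dye effect is not excluded.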
